A study of Drosophila melanogaster with 12 samples.

How the data were processed

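RNA of small pools of neuroblasts and ganglion mother cells (GMCs, the daughters that neuroblasts bud off) from the ventral nerve cord of Drosophila melanogaster embryos was compared with a common reference on spotted microarrays with a Cy3 and a Cy5 channel. Per the labels' protocols, embryos developed at 25 degrees C and cells came from stage 11. Between 50 and 100 cells were lysed per sample, and their RNA was reverse transcribed, tailed with terminal transferase, amplified by PCR and labelled by random priming. The reference was made the same way from about 30 whole w1118 embryos of stages 10 to 12. There were 12 arrays, 6 of the group called wildtype and 6 of the prospero mutant, and each array carried its own cell sample. Per the labels, the wildtype animals carried the pros17 allele over the TM3-KrGFP balancer chromosome, so they were heterozygous, and the mutant animals were homozygous for pros17. On replicates 1 to 3 of each group the cells were in Cy3 and the reference in Cy5, and on replicates 4 to 6 the dyes were exchanged. The labels do not say whether samples of a group came from separate embryos, so the p-values measure only the spread between these samples, part of which may be technical.

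The deposited values are log2 ratios, with 14569 probes on each of the 12 arrays. The scanner software, background correction and normalization are not given in the sources used here. The base of the logarithm was read from the values: where 1 channel had no signal, the levels lay at even steps after raising 2 to the deposited value on 6 of the 10 arrays that could be examined, within a mean miss of 0.1 of a step, and on 0 arrays for base e or base 10. Arrays of opposite dye orientation correlated above 0 in every pair, so the ratios had been turned before deposit. They are read here as cells over reference. This direction is likely and not stated in the labels. Its basis is the medians of the muscle, gut and epidermal lists against a whole-embryo reference. These were below 0 on every array but wildtype replicate 1 for muscle. The epidermal list was not among those named beforehand for this check. The hemocyte and fat body list was, and it went the other way. Its median was above 0 on every array but mutant replicate 5 (-0.002). Neuroblast factors had members on both sides of 0. The centring applied before deposit is not known; each column had a median of 0 as deposited, and between 22.1% and 38.6% of the probes of each array stood at exactly 0.

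An exact 0 was taken as a place with no ratio, and a value beyond 11 in size as a spot with signal in 1 channel only. Both were set to missing, which left between 8421 and 10030 ratios per array, with medians from -0.12 to 0.51 and SDs from 1.50 to 2.05 (log2). This step was added after the values had been looked at, and results with these values kept or held at 8 are among the alternatives. No spot intensities were used here, so dim spots could not be removed and the signal over background behind each ratio is unknown. The number of arrays also limits the precision.

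Probes were named through the platform annotation and looked up by gene identifier in the RefSeq gene table of the organism, which changed 0 symbols. Of the probes, 12657 had 1 gene symbol, 96 had several and 1816 had none in these tables; 12011 of the named probes were found in the gene table and 646 kept the platform's symbol. They stood for 11979 distinct genes, of which 436 had more than 1 probe. The name eIF4A alone was held by 128 probes. Probes of a gene were averaged per array, and probes with several or no symbols stayed as single rows. A row was tested when it had a ratio on at least 4 of the 6 arrays of each group. No coordinates are given because the build behind the array is not named.

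The comparison was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group and dye of the cells as terms, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A fitted difference can depart from the difference of the group means where missing values fall unevenly over the dyes. For 18 gene lists fixed before the data were examined, limma's camera was run in its preranked form on the moderated statistics, with a preset correlation of 0.01 between genes, because camera itself does not accept missing values. Lists needed 4 tested members, which 17 lists had; the midline list had too few. Camera with an estimated correlation and fry were run on the 6361 rows with all 12 values. For prospero, an exact permutation test over all splits of the arrays was added. The genes named in the text were chosen by a rule written before the data were examined: prospero, the 15 named genes with the largest fold in each direction among those past the threshold (genes known only by a CG or CR number if among the 5 largest), and up to 4 members of smallest p per list. Genes named outside that rule are said to be chosen after their values were seen. Many genes of the fixed lists are not analysed here.

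The fit was tested on simulated arrays of the comparison of mutant and wildtype, with 8165 genes, the measured spread and 200 genes changed. It recovered 32.0% of genes changed by 1 on the log2 scale and 66.0% of those changed by 2, and 8.41% of its calls were false. The simulated errors were independent between genes, with the same spread in both groups and no shift between dye orientations. These rates therefore need not hold for the calls on the real arrays. Simulated shifts of 3 between the wildtype arrays of the 2 dye orientations were recovered for 76.0% of the genes changed. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

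The alternatives planned before the data were examined were median centring, quantile normalization, no dye term, each dye orientation alone, the replicate number as a block, complete rows only, a filter of 2 values per group, single probes, a robust prior, array weights, leaving out the rows with the smallest ratios, leaving out each array in turn, other thresholds, and the other list tests. Added after seeing the data were other treatments of zeros and one-channel values, a limit of 8, and leaving out the wildtype arrays of either dye. With the dye term, leaving out the wildtype Cy5 arrays rests the group difference of each gene on the Cy3 arrays. Leaving out the wildtype Cy3 arrays rests it on the Cy5 arrays. To ask how often chance gives as much, the fit and the list tests were repeated on 100 drawn splits of the arrays into groups of 6; the count for each list by itself was added after the count of lists was seen.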

Results

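The data set held 12 arrays of neuroblasts and their daughter cells from the embryonic ventral nerve cord, 6 from animals labelled wildtype and 6 from prospero mutants. Prospero is a homeodomain transcription factor that is inherited by the ganglion mother cell when a neuroblast divides. The design asked which transcripts differ between these groups, each measured against the same whole-embryo reference. Values below are log2 ratios of cells over reference, and differences are mutant minus wildtype on the log2 scale. Each array gave between 8421 and 10030 ratios, and 8165 rows, 7055 of them named genes, could be tested. The number of arrays limits the precision. Within the mutant group, arrays correlated at 0.753 to 0.859 over probes. Within wildtype they correlated at 0.722 to 0.866 in the same dye orientation and at 0.515 to 0.743 in opposite orientations. Between the groups they correlated at 0.567 to 0.841 in the same orientation and at 0.549 to 0.784 in opposite orientations. The between-group medians, 0.7365 and 0.684, both lay above that of wildtype arrays in opposite orientations, 0.608.

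The prospero transcript (pros, chromosome arm 3R) was above the reference in all wildtype samples and below it in all mutant samples. Its ratio was 2.17 ± 0.99 (SD, n = 6) in wildtype and -2.99 ± 0.69 (SD, n = 6) in the mutant, a difference of -5.16 (SE 0.36, limma adjusted p = 5.68e-05), or 35.6-fold. Wildtype values ran from 0.88 to 3.29 and mutant values from -3.95 to -2.13, so the groups did not overlap. A two-sided exact permutation test of the mean difference gave p = 0.00216, the smallest that 924 splits can give. With the cells in Cy3 the difference was -5.71 (adjusted p = 0.00288), and with the cells in Cy5 it was -4.60 (adjusted p = 0.0121).

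Across all rows, 404 passed the threshold, of which 275 were lower in the mutant and 129 higher. Of these, 247 were lower and 96 higher by at least 2-fold. Next to prospero stood other transcription factors among the falls. The bHLH gene HLH3B fell by 4.57 (SE 0.33, adjusted p = 5.68e-05; -4.56 in Cy3 and -4.59 in Cy5), and the bHLH gene Fer2 fell by 4.33 (SE 0.51, adjusted p = 0.00191; -3.61 in Cy3 and -5.04 in Cy5). The homeobox gene Six4, with 6 wildtype and 4 mutant values, fell by 4.40 and toy, an eyeless relative, fell by 3.50. The 15 largest falls also included nSyb, which encodes a synaptic vesicle SNARE (difference -4.10, with -3.14 in Cy3 and -5.06 in Cy5), and qvr, which encodes a regulator of potassium channels and sleep (-4.09). Further genes among them were Task7, a potassium channel gene (-4.70), CanB, a calcineurin subunit gene (-3.33), and jus, in which mutations cause seizures (-3.43). The largest fall was that of ms(3)76Ba, from 0.54 ± 1.06 to -5.43 ± 0.67 (SD, n = 6 in each group), a difference of -5.97 (SE 0.48, adjusted p = 0.000127). This gene lies on chromosome arm 3L. The wildtype animals carried a balancer of chromosome 3, so background and mutation cannot be told apart for this fall. The remaining genes of the 15 were wry (-4.10), Csas (-3.66), Scgbeta (-3.36) and Ugt37D1 (-3.34), with adjusted p from 0.0114 to 0.0497. Ugt37D1 had 4 wildtype and 4 mutant ratios. It could be fitted in only 4 of the omissions of a single array and lost the call in 2 of them. Of the 15 genes, Six4, nSyb and Csas also lie on 3L, and pros, Task7, Fer2, jus and Scgbeta on 3R. The same limit holds for them. HLH3B, toy, wry, qvr, Ugt37D1 and CanB lie on other chromosomes.

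Among the genes that rose were regulators of cell division and of neuroblasts. CycE, the cyclin that drives entry into S phase, rose by 2.43 (SE 0.41, adjusted p = 0.0122), from -0.26 ± 1.26 to 2.16 ± 0.37 (SD, n = 6 in each group). The neuroblast repressor dpn rose by 2.06 (SE 0.37, adjusted p = 0.0158), and mira, which encodes the adaptor that carries Prospero protein to the daughter cell, by 2.04 (SE 0.39, adjusted p = 0.0181). With the cells in Cy3 the differences of CycE, dpn and mira were 1.42, 1.26 and 1.35 (adjusted p from 0.191 to 0.274), and with the cells in Cy5 they were 3.44, 2.86 and 2.73 (adjusted p from 0.00772 to 0.0337). Sox21b rose by 2.40, the spindle gene Wdr62 by 2.26, the GATA factor gene pnr by 2.20 and bowl, a zinc finger gene, by 2.02. The largest rises were those of Alp1, an alkaline phosphatase gene (4.25, SE 0.95, adjusted p = 0.0295), and CG13157 (3.96, SE 0.84, adjusted p = 0.0358). CG13157 had 4 wildtype and 5 mutant ratios, and its difference was 1.32 (adjusted p = 0.803) without a dye term. Over all alternatives its adjusted p ran from 0.0266 to 0.803. Of the wildtype Cy5 arrays only replicate 5 had a ratio for it (-4.97), so it had no fit in Cy5. In Cy3 its difference was 3.23 (limma adjusted p = 0.254). Its wildtype ratios ran from -4.97 to 5.36 and its mutant ratios from -0.86 to 7.72, so the groups overlapped. CG7294, CG14626, CG12986, vari, KP78b and Tsp42Ea rose by between 2.52 and 3.12.

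**Figure D1:**
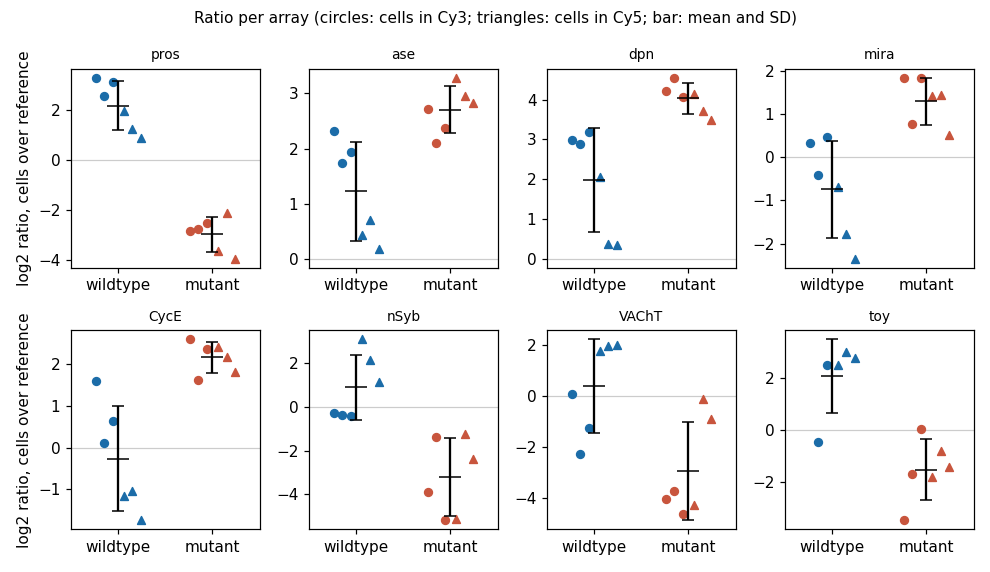
Log2 ratio of cells over reference on each array (vertical axis, log2) for 8 named genes in wildtype and prospero mutant samples; circles are arrays with the cells in Cy3, triangles with the cells in Cy5, and bars give the mean and SD of each group (n = 6, for toy 5 in wildtype). The pros values of the groups do not overlap, with wildtype down to 0.88 and mutant up to -2.13, and for ase, dpn, mira and CycE the wildtype triangles lie below the wildtype circles.

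The count of calls depended on which arrays and which scaling entered. With the cells in Cy3, 2 rows passed, pros and ms(3)76Ba, against 595 with the cells in Cy5; at an unadjusted p under 0.05 these numbers were 1087 and 2107. Leaving out the wildtype Cy5 arrays left 4 rows past the threshold (1132 at an unadjusted p under 0.05). Leaving out the wildtype Cy3 arrays gave 922. With the dye term, these fits estimate for each gene the same difference as the Cy3 and the Cy5 arrays alone. They differ only in spread and rows tested, so they are not separate checks. Without a dye term 187 passed, and with zeros and one-channel values kept 132 passed. With the replicate number as a block 106 passed. The count was 144 without wildtype replicate 5, 152 without wildtype replicate 6, 267 without mutant replicate 1, 117 without mutant replicate 4 and 161 without mutant replicate 6. Of 47 named genes past the threshold, prospero aside, 28 lost the call without at least 1 of the arrays, with 0 reversed. More omissions ended than kept the call for 13 of them, namely CG7294, Tsp42Ea, Sox21b, Wdr62, bowl, Task7, Csas, Scgbeta, ase, Galphai, zfh1, htl and CG13157. The median difference of all rows was -0.13, and after centring each array on its median it was 0.07. The split then turned from 275 lower and 129 higher to 219 lower and 392 higher, and after quantile normalization to 170 lower and 290 higher. Of the 404 rows, 375 could be fitted in both orientations. All 375 had the same direction in both, though rows that pass the pooled fit are selected for such agreement. The 127 higher ones had a median of 0.86 in Cy3 and 1.59 in Cy5, and the 248 lower ones of -1.35 and -2.22.

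The list of neuroblast identity factors passed with higher values in the mutant, through part of its members. Of 10 tested neuroblast identity factors, 3 rose, 0 fell and 7 did not pass; the 3 were dpn, ase (a proneural gene, 1.49, adjusted p = 0.0450) and klu (a zinc finger gene, 1.65, adjusted p = 0.0139). Adjusted over the list alone, 6 rose and 1 fell. The median difference of the list was 1.15 (camera adjusted p = 3.48e-05, and adjusted p = 0.241 with an estimated correlation). It was 0.51 with the cells in Cy3 (adjusted p = 0.0125) and 2.04 in Cy5 (adjusted p = 2.55e-05). For all lists, the p-values in 1 dye orientation or with arrays left out are camera's with the preset correlation of 0.01 only. Estimated over the rows with all 12 values, the correlation was 0.358 for neuroblast identity factors and 0.329 for asymmetric division. Such p-values are therefore likely too small. The list median per array averaged 2.02 on wildtype Cy3, -0.37 on wildtype Cy5, 2.17 on mutant Cy3 and 1.26 on mutant Cy5 arrays. Of 14 genes of the asymmetric division machinery, 2 rose, mira and Galphai (a G protein subunit of the spindle orientation complex, 1.23, adjusted p = 0.0382), and 12 did not pass; adjusted over the list alone, 5 rose. This list had a median of 0.68 (camera adjusted p = 4.64e-05, and adjusted p = 0.241 with an estimated correlation), with 0.38 in Cy3 (adjusted p = 0.0206) and 1.14 in Cy5 (adjusted p = 0.000143).

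Both cell cycle lists passed with higher values. Of 20 genes of DNA replication and the G1/S transition, 5 rose and 15 did not pass. The 5 were CycE, Sld5 (1.14), RnrL (a ribonucleotide reductase subunit, 1.46), Mcm2 (1.34) and Mcm5 (1.46, chosen after its values were seen), the last 2 being subunits of the replicative helicase. Adjusted over the list alone, 11 rose. The median of the list was 0.999 (camera adjusted p = 2.49e-11, and adjusted p = 0.241 with an estimated correlation), with 0.48 in Cy3 (adjusted p = 7.13e-05) and 1.71 in Cy5 (adjusted p = 4.60e-11). Of 18 genes of G2/M and mitosis, 3 rose, namely tum (a cytokinesis regulator, 1.33), CycB3 (1.30) and glu (a condensin subunit, 1.43), and 15 did not pass; adjusted over the list alone, 15 rose. The median was 1.03 (camera adjusted p = 2.49e-11, and adjusted p = 0.241 with an estimated correlation), with 0.34 in Cy3 (adjusted p = 0.000231) and 1.64 in Cy5 (adjusted p = 4.21e-11). Here the list median per array averaged 2.18 on wildtype Cy3, 0.69 on wildtype Cy5, 2.49 on mutant Cy3 and 2.42 on mutant Cy5 arrays. The estimated correlation was 0.464 for DNA replication and 0.600 for G2/M and mitosis, far above the preset 0.01 behind the p-values per orientation.

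The list of neuronal differentiation genes passed with lower values in the mutant, through part of its members. Of 18 tested, 3 fell and 15 did not pass. The 3 were nSyb and the genes for handling acetylcholine, VAChT (the vesicular transporter, -3.33, adjusted p = 0.0182) and ChAT (the synthesising enzyme, -2.77, adjusted p = 0.0242); adjusted over the list alone, 6 fell. The pan-neuronal gene elav was at 2.43 ± 0.74 in wildtype and 2.58 ± 0.54 in the mutant (SD, n = 6 each; chosen after its values were seen), with an adjusted p of 0.840. The list had a median of -0.75 (camera adjusted p = 0.00299, and adjusted p = 0.241 with an estimated correlation), with -0.53 in Cy3 (adjusted p = 0.0924) and -0.96 in Cy5 (adjusted p = 0.000836). It passed without each single array, with a median of -0.44 without mutant replicate 6, -0.49 without mutant replicate 3, -0.46 without wildtype replicate 4 and -1.03 at the lowest. Among 15 factors of GMC and neuronal fate, 4 homeobox genes fell, toy, Lim1 (-2.30), ap (-2.34) and zfh1 (-1.06), and 11 did not pass; adjusted over the list alone, 5 fell. The call for zfh1 was lost after median centring (-0.87, adjusted p = 0.0823), and its adjusted p ran from 0.0329 to 0.280 over all alternatives. The list itself did not pass with camera (median -0.28, camera adjusted p = 0.112) but did with fry (adjusted p = 0.0227). Its median ran from -0.71 to -0.34 without single arrays, and without wildtype replicate 2 it passed (-0.71, adjusted p = 0.0367; over all arrays, adjusted p = 0.397 with an estimated correlation). Of 7 glial markers, repo, the pan-glial homeobox gene, fell by 2.05 (adjusted p = 0.0237), while gcm and gcm2, which start glial development, had differences of -1.26 and -1.66 that did not pass. Adjusted over the list alone, 3 glial markers fell, and the list did not pass (median -0.60, camera adjusted p = 0.233).

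Markers of other tissues were measured to describe what else the samples held. Of 9 mesoderm and muscle markers, 1 fell, the FGF receptor gene htl (-1.78, adjusted p = 0.0470, and -1.58 with adjusted p = 0.0580 after median centring, in a range from 0.0157 to 0.398 over all alternatives), and 2 fell adjusted over the list alone. The list median was -1.38 (camera adjusted p = 0.00299, and adjusted p = 0.241 with an estimated correlation), with -1.40 in Cy3 (adjusted p = 0.00931) and -0.67 in Cy5 (adjusted p = 0.0514). Without the wildtype Cy3 arrays it was -0.53 (adjusted p = 0.124), where each gene's difference is again that of the Cy5 arrays alone. Wildtype replicate 1 stood at a list median of 0.78, where the other wildtype samples ran from -2.50 to -0.95 and the mutant samples from -4.03 to -2.12. Among 10 hemocyte and fat body markers, SPARC, an extracellular matrix gene, rose by 1.37 (adjusted p = 0.0158) and the list did not pass (median 0.59, camera adjusted p = 0.112, with 0.69 and adjusted p = 0.00167 in Cy3, and adjusted p = 0.973 in Cy5); adjusted over the list alone, 4 rose and 1 fell. It passed without wildtype replicate 6 (0.93, adjusted p = 0.0445) and without mutant replicate 5 (1.03, adjusted p = 0.0188), with a lowest median of 0.32 without wildtype replicate 2; over all arrays its adjusted p = 0.545 with an estimated correlation. Gut and yolk markers had a median of -0.54 (camera adjusted p = 0.738), and salivary gland and germline markers of -0.72 (camera adjusted p = 0.419). Without single arrays these medians ran from -0.81 to -0.15 and from -1.25 to -0.36, and neither list passed. Among 10 epidermal, tracheal and amnioserosa markers, pnr rose; the list median was -0.01, its mean 0.27 and its test pointed upward without passing (camera adjusted p = 0.328), and the median was 0.19 after median centring. The midline list had too few tested members.

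The remaining lists did not pass over all arrays. Temporal identity factors, which number the births of a neuroblast lineage, had a median of 0.91 (camera adjusted p = 0.111). Notch pathway and E(spl) genes had a median of 0.59 (camera adjusted p = 0.0600), which was -0.36 with the cells in Cy3 and 1.51 with the cells in Cy5 (adjusted p = 0.000159). Over both orientations its adjusted p = 0.545 with an estimated correlation. It passed without wildtype replicate 1 (0.92), wildtype replicate 3 (0.48), mutant replicate 2 (0.60) or mutant replicate 3 (0.77), with adjusted p from 0.0155 to 0.0435, and its median was 0.37 without wildtype replicate 5 and 0.38 without wildtype replicate 6. Within it E(spl)m6-BFM fell by 2.28 (adjusted p = 0.0139). Apoptosis regulators, ribosomal protein genes and heat shock genes had medians of -0.38, -0.22 and -0.46 (camera adjusted p = 0.738, 0.112 and 0.478), and 0 members of these lists passed in limma over all rows or adjusted over the list alone, with 2, 7 and 1 members at an unadjusted p under 0.05. The ribosomal list passed without wildtype replicate 3 (-0.26, adjusted p = 0.0138) or wildtype replicate 5 (-0.27, adjusted p = 0.0484); over all arrays its adjusted p = 0.555 with an estimated correlation. The heat shock median ran from -0.63 to -0.21 without single arrays, and was -0.22 in Cy3 and -0.99 in Cy5. In either dye orientation by itself the temporal, fate, glial, apoptosis, ribosomal and heat shock lists did not pass either, with a smallest adjusted p of 0.0924. In all, 6 of 17 lists passed with the preset correlation, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 7 with fry, which tests whether a list moves on balance 1 way without comparing it with other genes. Of 100 drawn splits of the arrays, 22 put 6 or more lists past the threshold, the real one included. Of the 18 splits that kept the wildtype Cy5 arrays together, 14 did so, against 8 of the other 82.

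**Figure D2:**
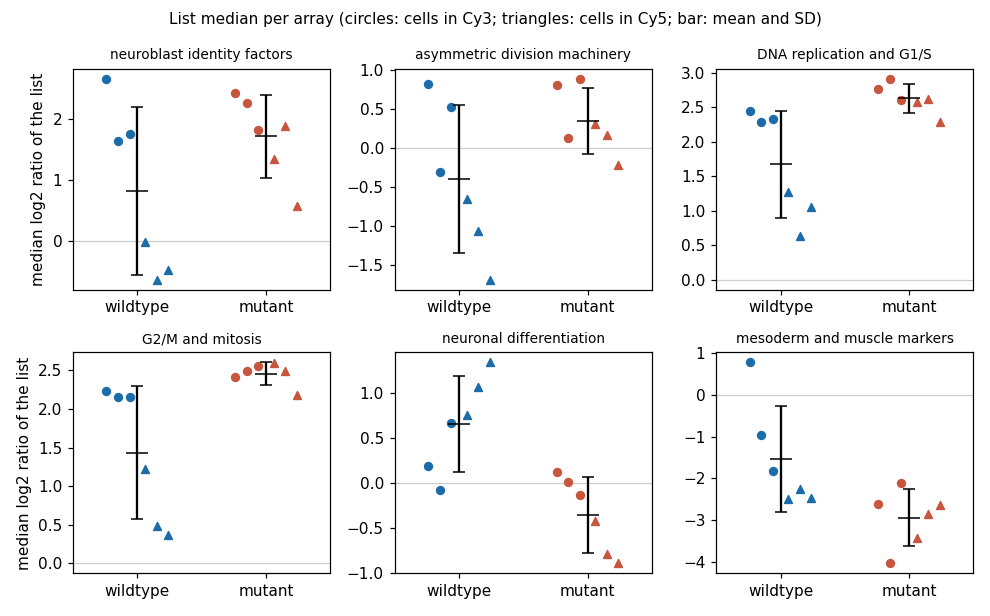
Median log2 ratio of cells over reference of the tested members of 6 gene lists on each array (vertical axis, log2) in wildtype and prospero mutant samples; circles are arrays with the cells in Cy3, triangles with the cells in Cy5, and bars give the mean and SD of each group (n = 6). For G2/M and mitosis the wildtype circles lie from 2.15 to 2.23 and the wildtype triangles from 0.37 to 1.22, while the mutant arrays of both orientations lie from 2.18 to 2.59.

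The wildtype arrays of the opposite dye orientations differed from each other. Between wildtype arrays with the cells in Cy5 and in Cy3, 1376 rows passed the threshold, 900 lower and 476 higher in Cy5, against 15 between the mutant arrays. Genes of G2/M and mitosis were lower on the wildtype Cy5 arrays (median -1.46, camera adjusted p = 1.42e-07, and adjusted p = 0.175 with an estimated correlation), as were neuroblast identity factors (-1.68, camera adjusted p = 0.000371, and adjusted p = 0.175 with an estimated correlation). In the mutant the corresponding medians were -0.18 (adjusted p = 0.733) and -0.56 (adjusted p = 0.585). The prospero transcript averaged 2.99 on the wildtype Cy3 arrays and 1.35 on the wildtype Cy5 arrays (difference -1.65, limma adjusted p = 0.0366). The difference between the mutant effects in the orientations, tested as an interaction, passed for 34 rows.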

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

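Both tests of a shared dye bias, the test with no shared arrays and the sorting of splits by the wildtype Cy5 arrays were chosen after the result was seen, and the per-list counts of splits were added after the count of lists in the splits was seen.

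The effect of the mutation differed between arrays with the cells in Cy5 and with the cells in Cy3 for several lists, by an interaction term in limma followed by camera. The median of the effect in Cy5 minus that in Cy3 was 1.15 for neuroblast identity factors (adjusted p = 0.00369), 1.17 for asymmetric division (adjusted p = 0.0146), 1.67 for Notch pathway and E(spl) genes (adjusted p = 0.000181), 0.94 for DNA replication (adjusted p = 8.58e-06) and 1.25 for G2/M and mitosis (adjusted p = 2.97e-07). It was -0.70 for neuronal differentiation (adjusted p = 0.0133), -0.71 for apoptosis regulators (adjusted p = 0.0365) and -0.85 for hemocyte and fat body markers (adjusted p = 0.0178). The medians of the Notch and apoptosis lists had opposite signs in the orientations, and the hemocyte list was higher in Cy3 (0.69) and near 0 in Cy5. With an estimated correlation the smallest adjusted p of these 8 lists was 0.243.

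These differences go with the wildtype arrays, where 1376 rows separated the dye orientations. A dye bias common to both groups is argued against as the whole cause, though not as a smaller part: the mutant arrays shifted by a median of 0.218 of the wildtype shift over those rows, a ratio lowered by their selection, and by 0.254 on average (0.199 to 0.331) of the shift in 9 pairs of wildtype arrays held out of the selection. Over all rows the shifts of the groups correlated at 0.266, and ribosomal protein genes were higher in Cy5 in both (0.11 and 0.21, adjusted p = 0.0220 and 0.0271, with the former at adjusted p = 0.558 with an estimated correlation). A difference in array scale as the whole cause is argued against too, since 70.9% of the rows stayed past the threshold after quantile normalization. A candidate explanation is that the wildtype samples on the Cy5 arrays held more neurons and fewer dividing progenitors, and it stays open: across genes outside the lists, which are not independent replicates, r was 0.263 between the wildtype shift and the mutant effect on the Cy3 arrays. Under the bound set before the test, r above 0, this would have counted against the explanation; that bound was found to be wrong only after the value was seen, since simulated unchanged arrays with the same shared samples gave 0.498. The covariance lay the other way, at 0.293 against 0.212 in the simulated arrays, so these values do not decide. With no array in both differences r averaged 0.0732 and ran from -0.0884 to 0.227 over the 3 ways of dividing the samples. The bound written for this test counted a mean r above 0 against the explanation, and the mean met it. The verdict was instead taken from all 3 ways, which fell on both sides of 0, so the explanation was left open against that bound.

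Mesoderm and muscle markers were lower in the mutant, with wildtype replicate 1 far above the rest. Without it the list median was still -1.14, so the lower median did not rest on that replicate alone. The list also passed there by camera with the preset correlation (adjusted p = 0.00843), the bound set before the test. That p carries little weight. Over all arrays, 12 of 100 splits gave this list a camera p as small, and its adjusted p was 0.241 with an estimated correlation. Without replicate 1 the list medians per array overlapped, from -2.50 to -0.95 in wildtype and from -4.03 to -2.12 in the mutant. Mesodermal cells in varying amounts in the wildtype samples may contribute, and cannot be told apart from a change in the cells themselves: the mean correlation of members across the 6 wildtype arrays lay at percentile 72.0 of 10000 random lists matched on spread. Without the wildtype Cy3 arrays, where each gene's difference is that of the Cy5 arrays alone, the list did not pass (median -0.53, adjusted p = 0.124). Members differed in wildtype level, from 1.53 for twi to -1.73 for Mlc1, -4.78 for Mlc2 and -4.87 for up (Mlc1 and Mlc2 chosen after their values were seen).

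Of 100 drawn splits of the 12 arrays, 1, the real one, gave as many genes as 404, and the highest of the others gave 4. This argues against no difference between the groups, provided the samples can be exchanged, which the labels do not show. It does not test the size of the count, because the other splits mix the genotypes and take their difference as spread. The split by dye was left out of the draw. With 1376 rows separating the wildtype dye sets, a structure of the samples is not excluded. For the number of lists chance cannot be excluded: 22 of 100 splits gave as many as 6, and the highest of the others gave 10. Of the 18 splits that kept the wildtype Cy5 arrays together, 14 gave as many, against 8 of the other 82, which points to a structure of the samples. List by list, the count of permutation splits with a camera p as small was 1 for DNA replication (p = 1.50e-12, smallest other 2.27e-11) and 3 for G2/M and mitosis (p = 2.93e-12, smallest other 5.83e-13), both under the share of 0.05 that was set, although another split gave G2/M a smaller p and both lists were at an adjusted p of 0.241 with an estimated correlation. Over the same permutation splits it was 5 for neuroblast identity (p = 6.13e-06, smallest other 7.07e-07), 11 for asymmetric division (p = 1.09e-05, smallest other 1.23e-08), 5 for neuronal differentiation (p = 0.00106, smallest other 8.07e-05) and 12 for mesoderm and muscle (p = 0.001, smallest other 1.52e-06), where chance is not excluded.

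Single samples stood far from the others of their group in 10 of 160 groups tested, where chance alone gives about 8. Mutant replicate 3 had the lowest values for Task7 (-9.12, next -2.47), Six4 (-5.93, next -3.32) and bowl (-1.80, next -0.55). Mutant replicate 2 had the highest values for CG7294 (0.40, next -0.70) and Wdr62 (0.82, next -0.32), and mutant replicate 4 for Mcm2 (4.67, next 3.48). Wildtype replicate 4 had the highest values for CG14626 (0.64, next -1.88) and vari (-2.49, next -4.70). Wildtype replicate 2 was lowest for toy (-0.47, next 2.49) and highest for the list median of salivary gland and germline markers (0.21, next -2.16).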

How the results depend on the processing

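Treatments of zeros and one-channel values and leaving out wildtype arrays of 1 dye were chosen after seeing the data; the others were planned. Prospero kept its direction and its side of the threshold in every setting run, from -5.71 to -4.60, and from -5.47 to -5.03 without single arrays. The 404 calls kept their direction wherever they could be fitted, except 2 of them with zeros and one-channel values kept. The number of lists past the threshold stayed between 6 and 8 except with an estimated correlation (0), and ran from 6 to 8 without single arrays.

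The number of genes, then those higher and lower, changed as follows; except where fewer samples or another threshold entered, the cause was not tested. Median centring gave 611 and 392 higher, with 347 of the 404 shared. Quantile normalization gave 460 (290 and 170), no dye term 187 (51 and 136), cells in Cy3 alone 2 (0 and 2) and cells in Cy5 alone 595 (205 higher). Array weights gave 206 higher among 569. An adjusted p of 0.01 gave 43 (7 and 36) and of 0.1 gave 1149 (426 and 723). Keeping zeros and one-channel values gave 132 (56 and 76). Without the wildtype Cy5 arrays 4 passed (0 and 4), and without the wildtype Cy3 arrays 922 (388 and 534). For each gene these fits estimate the same difference as the Cy3 and the Cy5 arrays alone, so they are not separate checks. Without single arrays the count ran from 117 to 549, with 28 to 209 higher and 89 to 340 lower.

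With the replicate number as a block, 106 genes passed (24 higher and 82 lower) and 6 lists. The samples were taken to share only a number, which the values do not settle. Deviations of same-numbered arrays from their group means correlated at 0.0636 to 0.285, over 0.1 in 4 of 6 pairs. Taken from the means of group and dye, the deviations correlated at 0.0622 to 0.262. That 5 of 12 arrays correlated best with their own number is a hint from the data, not the design. Of the named genes, 27 were past the threshold without the block and not with it.

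The median or the direction of the test turned in these cases. Notch pathway genes were at -0.36 on Cy3 arrays and without the wildtype Cy5 arrays, apoptosis regulators at 0.16 in the same settings and -0.20 without mutant replicate 5, where the test points upward (-0.51 to -0.20 over single arrays left out). Gut and yolk markers were at 0.19 on Cy5 arrays and without the wildtype Cy3 arrays, and salivary gland and germline markers at -0.18 on Cy5 arrays, the latter with an upward test. The hemocyte list was at 0.033 without the wildtype Cy3 arrays, where only its test pointed downward, and mam at 1.28 with zeros and one-channel values kept. Epidermal, tracheal and amnioserosa markers had a median of -0.01 over all arrays. It was 0.33 on Cy3 arrays, 0.11 on Cy5 arrays, 0.19 after median centring, 0.24 after quantile normalization and 0.13 without a dye term. Without single arrays it ran from -0.16 to 0.30. Settings without the wildtype arrays of 1 dye repeat the gene differences of the other dye's arrays. The cause of these turns was not tested. The apoptosis list had too few members once rows with the smallest ratios were left out, so it has no value there. Signal over background, which is unknown here, limits all ratios of weak spots.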

Other observations

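The genes named in this part were chosen after their values were seen, as was the split of chromosome 3 by direction and size. Within the wildtype group, 8 genes of the Notch pathway and E(spl) list were lower on the Cy5 than on the Cy3 arrays and 1 was higher. Brd differed by -6.52 (limma adjusted p = 0.00232), E(spl)m4-BFM by -5.48 (adjusted p = 0.00232), E(spl)mdelta-HLH by -3.78 (adjusted p = 0.00152) and Tom by -3.70 (adjusted p = 0.00351). In the mutant the same differences were -0.21, -0.30, -0.58 and -0.67, with adjusted p from 0.518 to 0.926. The higher one was E(spl)m6-BFM (1.86, adjusted p = 0.0183). The list had a wildtype median of -2.14 (camera adjusted p = 0.000304, and adjusted p = 0.175 with an estimated correlation). Neuronal differentiation genes went both ways, with 4 higher on the Cy5 arrays, among them ChAT (2.20, adjusted p = 0.0228) and brp, a gene of synaptic active zones (2.77, adjusted p = 0.0198), and 2 lower, side (-3.72, adjusted p = 0.0194) and robo1 (-1.68, adjusted p = 0.0164). That list did not pass between the wildtype sets (median 0.25, camera adjusted p = 0.174).

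Signal in the cell channel, with or without a ratio, was present in at least 5 more mutant than wildtype arrays for 14 rows. Among them were bam, FANCI and lms. It was present in at least 5 more wildtype arrays for 3 rows, among them CG13245. The share of probes at exactly 0 differed between arrays, from 22.1% on mutant replicate 3 to 38.6% on wildtype replicate 1. These counts do not take that into account. By Fisher's exact test 0 of these passed after adjustment over 13891 genes and probes (smallest adjusted p = 1), while each had an unadjusted exact p of 0.0152 or, for CG7093, 0.00216.

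The groups also differ in their chromosomes, as the wildtype animals carried a balancer of the third chromosome. Among called genes with a known chromosome, 178 of 340 lay on chromosome 3 (52.4%, against 43.8% of the genes not called; odds ratio 1.41, Fisher's exact p = 0.00206, interval 1.13 to 1.77). By the same exact test the odds ratio was 1.93 (p = 0.000852) for genes higher in the mutant, 1.21 (p = 0.179) for lower genes and 1.09 (p = 0.659) for genes changed at least 4-fold; these were not compared with each other. A background difference of that chromosome may contribute to some calls. The odds ratio of all called genes fell between the bounds of 1.2 and 1.5 set before the test, so the test does not decide. That of the genes higher in the mutant lay above 1.5 (interval 1.29 to 2.91), in a split chosen after the values were seen. For a single gene, background and mutation cannot be told apart, because the groups differ in both.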
